A study of Homo sapiens with 58 samples.

How the data were processed

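MicroRNAs (miRNAs) were measured by sequencing in frozen biopsies of the duodenal mucosa, the lining of the first part of the small intestine. The 58 libraries fell into 37 from patients with functional dyspepsia, a disorder of upper abdominal symptoms without a structural cause, and 21 from healthy controls. Groups were taken from the sample labels. Per the labels, RNA was extracted with TRIzol and a silica column. The labels' protocol then describes a stranded total RNA kit with paired-end reads, and how the small RNA libraries were made is not given in the sources used here. Each control carries a label that its data belong to another series as well, and no patient does. Deposited series and group therefore cannot be told apart, and the labels do not say whether patient and control libraries were prepared or sequenced together. Sample titles begin with a number whose meaning the labels do not give, with 4 such numbers among the patients and 4 others among the controls.

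The authors deposited 1 table of expected counts, in which a read that matched several places had, as inferred here, been shared between them. Of its non-zero values 77.1% were whole to within 1e-09, and the values that were not whole point to such sharing. The sources used here do not state it, and the sum over precursors described below rests on it. The table held 2822 rows, each a mature miRNA on a precursor, with 2588 mature names and 1881 precursors. Bowtie and the genome build hg38 are named per the submitters' processing notes, with no version. The counting program, adapter trimming and miRNA annotation are not given in the sources used here. Multiple mapping affects members of families with similar sequences most, since any split between them was set by the authors' counting.

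From the table, 2 repeated rows were dropped and the rows of a mature miRNA were summed over its precursors, which concerned 168 mature names, and then rounded to whole numbers. Of the 2588 mature names, 1998 had a count. Library totals ran from 3660396 to 15076048 counts. miRNAs were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with robust estimation, TMM factors, edgeR's filter on low counts and a two-sided Benjamini-Hochberg threshold of 0.05. The filter left 519 miRNAs with 99.978% of the counts. Levels are given as CPM (counts scaled to a common library size of 1e+06) with the TMM factors, with mean ± SD. A log2 fold change is patients over controls, and its SE was derived from the test statistic. Because the labels do not state in words that every library came from a different person, p-values measure the spread between these libraries, taken as 1 per person.

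Before the data were examined, 16 lists of miRNAs were fixed. They covered the intestinal epithelium, enteroendocrine and secretory cells, smooth muscle and fibroblasts, endothelium, lymphocytes and other leukocytes, myeloid cells, red blood cells, neurons and glia, exocrine pancreas and liver, the epithelial barrier, NF-kB and inflammation, serotonin and visceral pain, the miR-17-92 family, the let-7 family, the imprinted cluster of chromosome 14, and p53 and hypoxia. The 14 lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and with camera at an estimated correlation and fry as alternatives. The test of camera compares a list with all other miRNAs, and fry asks whether its members move on balance in a common direction. Some miRNAs were on several lists. The miRNAs named were the 12 higher and 12 lower with the smallest p among those past the threshold, the 10 with the highest mean CPM, and up to 4 tested members of each list with the smallest p. Others are named only where said to be chosen after their values were seen, or as members of a list that is described.

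Measures per library (total, number of miRNAs detected after thinning to the smallest library's total, share of the 10 most abundant miRNAs, and spread around the group median) were compared with two-sided permutation tests of 100000 resamples, and adjusted over these 4 measures. Precursor positions came from GENCODE release 29, on the same build, in which 1876 of the 1881 precursors were found (99.7%). Their GC content was computed from the sequence of that build. Libraries of a group were compared pairwise over miRNAs with a mean count of at least 50. The lowest dispersion index of a pair was 67.9 in patients and 86.8 in controls, far above sampling noise, so no library was a copy of another of its group. Libraries of different groups were not compared in this way.

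Alternatives covered normalization (DESeq2 size factors, library totals only, upper quartile factors), filters, covariates (surrogate variables from sva 3.50.0, a tissue score, the leading number of the title), the test (DESeq2 1.42.0, limma-voom, edgeR without robust estimation, a rank-sum permutation test), the threshold and the definitions of the library measures. Thinned libraries, removal of a trend on GC content, omission of the furthest library of each group, rows kept apart and a red blood cell score were added after the data were seen. The steps were tested on simulated data with the sample sizes and levels of this comparison. With 519 miRNAs, 93% of those changed 1.5-fold and 99% of those changed 2-fold were called, 4.48% of calls were false, and 0 calls were made when nothing was changed. Simulated changes went up as often as down, and no difference in library preparation was simulated. These rates therefore do not cover errors from normalization or from such a difference.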

Results

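MicroRNA profiles of duodenal mucosal biopsies were compared between 37 patients with functional dyspepsia and 21 healthy controls. The series addresses the mucosal barrier of the duodenum in this disorder, and the comparison asks which miRNAs differ in level between patients and controls. Patient libraries held 3660396 to 13505102 counts (median 6648246) and control libraries 4050037 to 15076048 (median 9013661). On the log2 scale the difference in mean total, patients minus controls, was −0.34 (n = 37 and 21; permutation p = 0.00798, adjusted p = 0.0106). Every control, and no patient, was labelled as also belonging to another series, so group and deposited series cannot be told apart in any comparison here. Whether the libraries were also prepared apart is not stated.

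The most abundant miRNAs in both groups were those typical of gut epithelium. miR-192-5p and miR-215-5p, which HNF4A keeps high in enterocytes, held on average 17.8% and 10.6% of a library's counts over all 58 libraries. miR-148a-3p held 9.25%, miR-143-3p of smooth muscle and fibroblasts 7.08% and miR-194-5p 6.68%, and of this last pair miR-143-3p had the higher mean CPM in controls and miR-194-5p in patients. miR-148a-3p was 1.58-fold lower in patients (edgeR, adjusted p = 1.63e-07), and miR-26a-5p was 1.18-fold lower but 0.16 higher on the log2 scale with library totals only. The 10 most abundant miRNAs of a library took 68.7% ± 2.75 (SD, n = 37) of its counts in patients and 72.4% ± 2.36 (SD, n = 21) in controls. The means differed (permutation p = 1e-05, the smallest the resamples can give, and adjusted p = 2e-05). The ranges overlapped, with 62.2% to 74.6% in patients and 68.7% to 77.1% in controls. At a common depth, 918 ± 26.2 miRNAs were detected in patients and 866 ± 22.3 in controls (permutation p = 1e-05, adjusted p = 2e-05). The spread of a library around its group was 0.444 ± 0.110 log2 units in patients and 0.496 ± 0.119 in controls, which did not pass the test (permutation p = 0.096).

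Patients and controls formed separate groups along the first principal component, which held 29.6% of the variance and of which group explained 93.0%. Scores ran from 2.96 to 7.11 in patients and from −13.2 to −0.18 in controls.

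**Figure D1:**
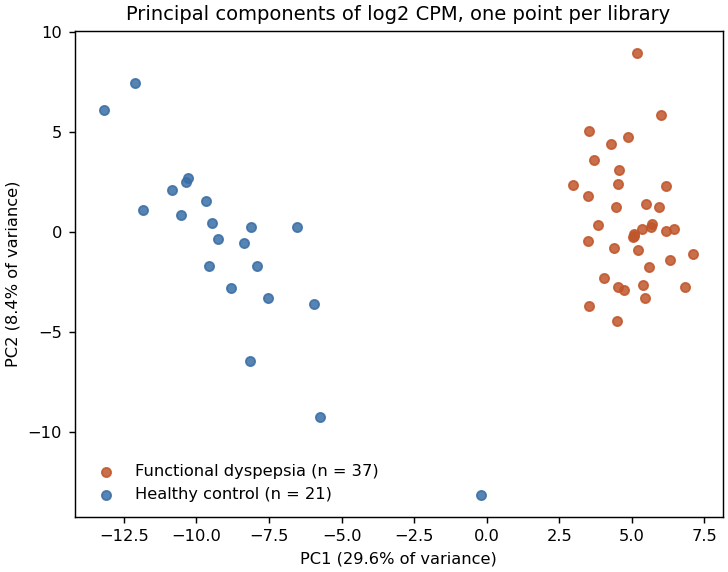
First 2 principal components of log2 CPM over the tested miRNAs, with 1 point per library, patients in orange (n = 37) and controls in blue (n = 21). The groups do not overlap on the first component (29.6% of the variance), and the control nearest to the patients has a score of −0.18.

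Of 519 miRNAs tested, 351 (67.6%) differed between patients and controls, with 166 higher and 185 lower in patients (edgeR, adjusted p threshold 0.05). Most differences were modest. Of the 351, 37 differed at least 2-fold, 19 of them higher and 18 lower, and 172 differed by less than 1.5-fold. The median absolute log2 fold change among them was 0.59. For 8 of the 519 no patient library overlapped with any control library, which for any single miRNA happens in 5.98e-14% of splits of these sizes. With library totals in place of TMM factors the median log2 fold change of all tested miRNAs moved from 0.04 to 0.44, and 77.9% of calls were higher in patients against 47.3% with TMM factors. Directions given here are therefore relative to the bulk of miRNAs.

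**Figure D2:**
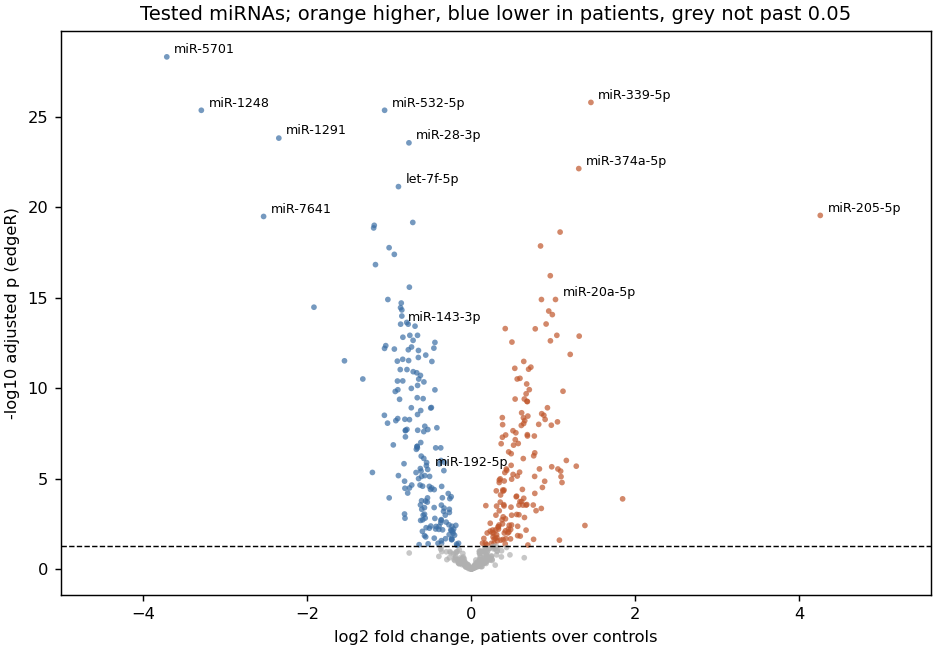
Log2 fold change of patients over controls (x axis) against −log10 of the adjusted p from edgeR (y axis) for the 519 tested miRNAs. Orange points are the 166 higher and blue points the 185 lower in patients, and the dashed line marks an adjusted p of 0.05.

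Among the miRNAs higher in patients, miR-339-5p rose most clearly, 2.75-fold, from 65.7 ± 11.6 CPM in controls to 181 ± 31.1 CPM in patients (SD; log2 fold change 1.46, SE 0.07; edgeR, adjusted p = 1.55e-26). Its precursor lies in an intron of C7orf50 on chromosome 7, 1022933 to 1023026, on the minus strand (GRCh38, GENCODE 29). miR-374a-5p rose 2.48-fold (log2 fold change 1.31, SE 0.08; edgeR, adjusted p = 7.05e-23), and its precursor lies in an intron of the non-coding gene FTX on chromosome X, 74287286 to 74287357. Both were above the control median in 37 of 37 patient libraries. miR-32-5p, from an intron of TMEM245, rose 2.12-fold, and miR-140-5p, a miRNA of cartilage and fibroblasts from an intron of WWP2, rose 1.80-fold. let-7a-3p (1.95-fold), miR-141-5p (1.98-fold), miR-497-5p (1.88-fold), miR-335-5p (1.81-fold, from an intron of the imprinted gene MEST) and miR-186-5p (1.33-fold) also rose.

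The steepest increase, in a rare miRNA, was that of miR-205-5p, which is known from squamous epithelia. It had 976 counts over the patient libraries, with a count in 37 of 37, and 26 counts over the control libraries, with a count in 9 of 21. Its level was 3.42 ± 1.44 CPM in patients and 0.149 ± 0.244 CPM in controls (log2 fold change 4.26, SE 0.29; edgeR, adjusted p = 2.74e-20). Its precursor lies in an exon of MIR205HG on chromosome 1, 209432133 to 209432242. miR-203a-3p, also abundant in squamous epithelia, was lower in patients (log2 fold change −0.90).

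Among the miRNAs lower in patients, miR-532-5p fell 2.08-fold, from 1502 ± 250.2 to 723 ± 81.1 CPM (SD; log2 fold change −1.06, SE 0.05; edgeR, adjusted p = 4.21e-26). Its precursor lies in an intron of CLCN5 on chromosome X, 50003148 to 50003238. miR-28-3p fell 1.69-fold and lies in an intron of LPP on chromosome 3, 188688781 to 188688866. miR-30d-5p (1.64-fold), miR-30c-2-3p (2.27-fold), miR-629-5p (2.28-fold, in an intron of TLE3) and miR-99b-3p (2.00-fold) were lower as well. All 6 lay below the control median in 37 of 37 patient libraries.

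The largest decreases were in rare entries. miR-5701, which has 3 precursors on chromosome 15, was 12.3 ± 4.29 CPM in controls and 0.939 ± 0.495 CPM in patients (log2 fold change −3.71, SE 0.17; edgeR, adjusted p = 4.68e-29). miR-1248 fell 9.78-fold, miR-1291 5.08-fold and miR-7641 5.78-fold. miR-1248 overlaps the small nucleolar RNA gene SNORA81 within EIF4A2, and miR-1291 overlaps SNORA2C within KANSL2. Of the precursors of miR-7641, mir-7641-2 overlaps a 5S ribosomal RNA pseudogene and mir-7641-1 shares 20 bases with it. Reads of miR-1248, miR-1291 and miR-7641 can therefore come from those RNAs.

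In the intestinal epithelium list, 4 of 10 miRNAs rose, 4 fell and 2 did not pass the test, while with library totals only 7 were higher and 2 lower. Its camera test did not pass (adjusted p = 0.708). miR-192-5p fell from 228340 ± 59480 to 158110 ± 40217 CPM (log2 fold change −0.53, SE 0.10; edgeR, adjusted p = 3.06e-06), a call that ended with library totals only (log2 fold change −0.12). miR-215-5p fell 1.58-fold and miR-203a-3p, a miRNA of differentiating epithelium, 1.86-fold. miR-194-5p, made from the same clusters as miR-192 and miR-215, rose 1.32-fold from 54705 ± 14272 to 72041 ± 17308 CPM. miR-141-3p (2.31-fold), miR-31-5p (1.61-fold) and miR-429 (log2 fold change 0.68) rose, and the first and the last belong to the miR-200 family that keeps cells epithelial. miR-200b-3p of that family was slightly lower (log2 fold change −0.17, SE 0.08; edgeR, adjusted p = 0.0492), a call that ended in 12 of 19 alternatives, among them the DESeq2 test, limma-voom and thinned libraries, and with library totals only it was called higher (log2 fold change 0.24). As shares of the library totals, the members together held 40.3% ± 6.49 of the counts in patients and 39.2% ± 5.99 in controls. These shares leave out the TMM factors, so they are not on the scale of the CPM values above.

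**Figure D3:**
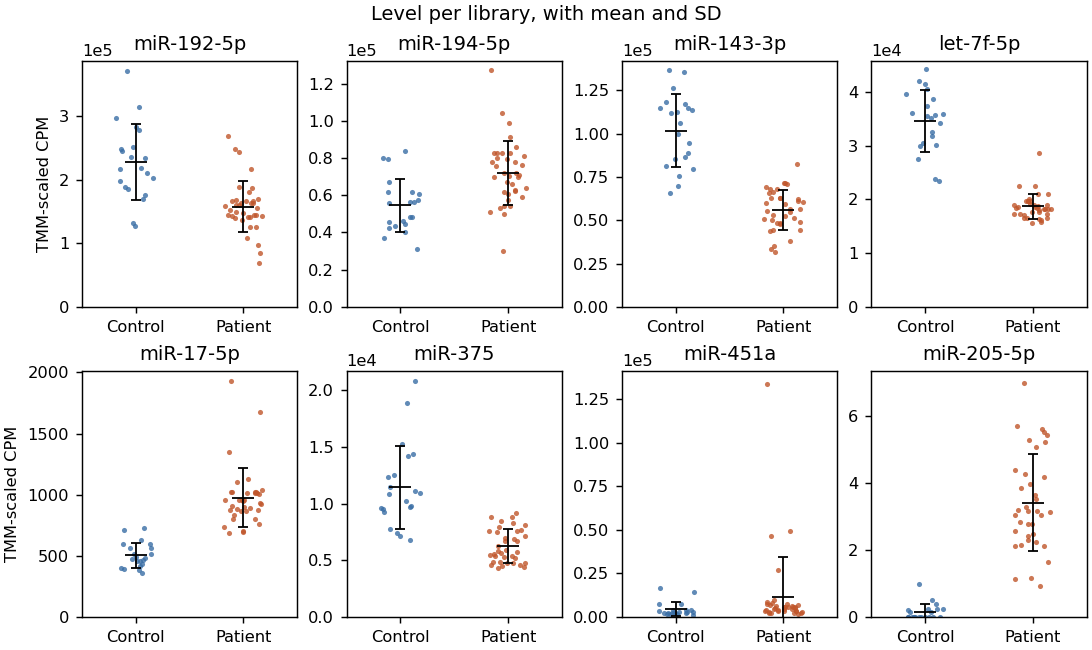
TMM-scaled CPM of 8 miRNAs, with 1 point per library (37 patients in orange, 21 controls in blue) and mean ± SD in black. miR-192-5p, miR-143-3p, let-7f-5p and miR-375 are lower in patients relative to the bulk of miRNAs, miR-194-5p, miR-17-5p, miR-451a and miR-205-5p are higher, and a few patient libraries reach far higher levels of miR-451a than the rest.

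Of the 5 enteroendocrine and secretory miRNAs, 4 fell and 1 rose, with a median log2 fold change of −0.81 and the same counts with library totals only. The list did not pass camera (adjusted p = 0.341). miR-375, abundant in enteroendocrine and goblet cells, fell from 11422 ± 3647 to 6272 ± 1479 CPM (log2 fold change −0.86, SE 0.10; edgeR, adjusted p = 9.18e-12). miR-7-5p fell as well (log2 fold change −0.59). miR-182-5p and miR-183-5p fell 1.75-fold and 1.83-fold, whereas miR-96-5p of the same cluster rose (log2 fold change 0.82).

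Markers of other cell types moved in both directions, and none of their lists passed camera. Of 13 miRNAs of smooth muscle and fibroblasts, 3 rose, 3 fell and 7 did not pass (camera adjusted p = 0.938), while with library totals only 8 were higher and 1 lower. miR-143-3p fell from 101530 ± 20986 to 55930 ± 11723 CPM (log2 fold change −0.86, SE 0.08, edgeR adjusted p = 2.83e-14). Its cluster partner miR-145-5p was 4314 ± 1079 CPM in controls and 3975 ± 948.3 CPM in patients and did not pass (edgeR, adjusted p = 0.268). With library totals only miR-145-5p was called higher (log2 fold change 0.28). miR-133a-3p and miR-199a-5p rose 1.31-fold and 1.27-fold. miR-1-3p fell 1.29-fold, but was 0.04 higher on the log2 scale with library totals only. miR-199a-3p and miR-199b-3p share their mature sequence and kept a near-constant ratio in the table (SD of the log2 ratio 0.0012), so their values are not independent.

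Of 5 endothelial miRNAs, 4 rose and 1 fell (camera adjusted p = 0.708). miR-126-5p rose 1.46-fold, miR-218-5p 1.41-fold and miR-139-5p 1.28-fold, and miR-139-3p, from the other arm of that precursor, fell 1.68-fold. Of 7 leukocyte miRNAs, 2 rose, 2 fell and 3 did not pass (camera adjusted p = 0.708), while with library totals only 5 were higher and 0 lower. miR-142-3p rose 1.95-fold and miR-142-5p 1.23-fold. miR-146a-5p and miR-342-5p were lower by 1.20-fold and 1.27-fold, and both lay above 0 with library totals only (log2 fold changes 0.13 and 0.05). miR-342-5p also lost its call with limma-voom, with the rank-sum permutation and in thinned libraries. The myeloid list had 2 tested members. miR-223-5p fell 1.69-fold, and miR-223-3p was 92.3 ± 24.7 CPM in controls and 100.3 ± 39.9 CPM in patients, which did not pass (edgeR, adjusted p = 0.362) except with library totals only.

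Of 4 red blood cell miRNAs, 3 rose and 1 did not pass (camera adjusted p = 0.708), while with library totals only 4 were higher. miR-451a was 11342 ± 23267 CPM in patients, with a median of 5318 CPM, and 4338 ± 4030 CPM in controls, with a median of 3033 CPM (log2 fold change 1.39, SE 0.43; edgeR, adjusted p = 0.00385), and its log2 fold change was 0.94 without the furthest library of each group. miR-144-5p rose from 18.9 ± 14.7 CPM (median 13.8) to 68.3 ± 148 CPM (median 28.2), with a log2 fold change of 1.85 that was 1.28 without those libraries. Over 19 alternatives each, miR-451a ran from 0.22 to 1.82 and miR-144-5p from 0.66 to 2.28, with their calls kept. A red blood cell score built from these same miRNAs was among the alternatives. miR-144-3p rose 2.11-fold. With the direction kept, this call ended in 8 of 18 alternatives, among them the DESeq2 test, limma-voom, the rank-sum permutation and omission of the furthest libraries. In 1 more, the red blood cell score, its sign changed (log2 fold change −0.0044). miR-486-5p had a higher mean but a lower median in patients (215 against 333 CPM) and did not pass (edgeR, adjusted p = 0.234), but was called higher with library totals only (log2 fold change 1.09; adjusted p = 0.0399) and lower by the rank-sum permutation (−0.28). Of 5 neural miRNAs, 2 rose, 2 fell and 1 did not pass (camera adjusted p = 0.744), while with library totals only 3 were higher and 2 lower. miR-9-5p and miR-129-5p fell 2.06-fold and 2.08-fold, and miR-9-3p and miR-137 rose 1.55-fold and 1.81-fold. None of the miRNAs of exocrine pancreas and liver was abundant enough to be tested, and miR-122-5p of liver had 92 counts over all libraries.

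Of 14 miRNAs described as acting on tight junctions or permeability, 7 rose, 4 fell and 3 did not pass (camera adjusted p = 0.708), while with library totals only 10 were higher and 2 lower. miR-29a-3p, which has been tied to raised intestinal permeability, rose from 2416 ± 338 to 3409 ± 359 CPM (log2 fold change 0.50, SE 0.05; edgeR, adjusted p = 2.77e-13). miR-874-3p rose 1.51-fold, while miR-101-3p and miR-34c-5p fell 1.72-fold and 1.87-fold. miR-21-5p fell 1.25-fold, but was 0.08 higher on the log2 scale with library totals only.

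Of 10 miRNAs induced in inflammation, none rose, 8 fell and 2 did not pass, but the list did not pass camera (adjusted p = 0.189), and with library totals only 2 were higher and 2 lower. miR-146b-5p fell from 9226 ± 2105 to 5418 ± 895 CPM (log2 fold change −0.77, SE 0.07; edgeR, adjusted p = 2.83e-14). miR-212-3p fell 1.37-fold, a call that ended with library totals only (log2 fold change −0.05). Of 5 miRNAs tied to serotonin signalling or visceral pain, 3 rose and 2 did not pass (camera adjusted p = 0.506), while with library totals only 5 were higher. miR-16-5p rose 1.70-fold and miR-24-3p 1.30-fold. miR-103a-3p was 3609 ± 529 CPM in controls and 3363 ± 594 CPM in patients and did not pass (edgeR, adjusted p = 0.136), but was called higher with library totals only (log2 fold change 0.30), and lower with upper quartile factors (−0.13), without the furthest library of each group (−0.13) and with a red blood cell score (−0.16). Of 4 miRNAs of p53 and hypoxia, miR-34c-5p fell and 3 did not pass (camera adjusted p = 0.792). Among the latter, miR-34a-5p was 74.4 ± 59.4 CPM in controls and 71.2 ± 28.7 CPM in patients, and the log2 fold changes of miR-210-3p and miR-34b-3p were 0.15 and 0.32. With library totals only the last pair was called higher (0.57 and 0.73).

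The let-7 family, whose members rise with differentiation, was lower in patients as a group. Of 9 members 7 fell, none rose and 2 did not pass, with a median log2 fold change of −0.49 (camera adjusted p = 0.00189; adjusted p = 0.446 with an estimated correlation). let-7f-5p fell from 34552 ± 5702 to 18686 ± 2366 CPM (log2 fold change −0.89, SE 0.06; edgeR, adjusted p = 7.01e-22). let-7i-5p fell 1.91-fold, let-7g-5p 1.57-fold and let-7b-5p 1.37-fold, the last with a call that ended with library totals only. With library totals only 2 members were higher and 4 lower (camera adjusted p = 0.0529). Members differ by few bases, so reads can have been shared between them.

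The miR-17-92 family, made from related clusters tied to proliferation, was higher as a group. Of 14 members 10 rose, 3 fell and 1 did not pass, with a median log2 fold change of 0.74 (camera adjusted p = 0.0135; adjusted p = 0.767 with an estimated correlation). miR-20a-5p rose from 809 ± 212 to 1649 ± 353 CPM (log2 fold change 1.03, SE 0.09; edgeR, adjusted p = 1.22e-15) and miR-17-5p 1.93-fold. Their precursors lie in MIR17HG on chromosome 13, at 91351065 to 91351135 and 91350605 to 91350688. miR-19a-3p and miR-19b-3p rose 1.72-fold and 1.62-fold, while miR-92a-3p of the same cluster fell (log2 fold change −0.32), though not with library totals only. With a red blood cell score as a covariate the list did not pass (camera adjusted p = 0.0820), although miR-17-5p and miR-20a-5p kept log2 fold changes of 0.87 and 0.97.

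The imprinted cluster of chromosome 14, which in adults is mainly expressed in mesenchymal cells, had members that changed in both directions. Of 33 members 15 rose, 11 fell and 7 did not pass (camera adjusted p = 0.789), while with library totals only 21 were higher and 5 lower. miR-127-3p fell from 835 ± 159 to 465 ± 88.6 CPM and miR-379-5p fell 1.78-fold. miR-409-3p fell 1.91-fold while miR-369-3p rose 2.06-fold, although both precursors lie in an intron of MEG9, at 101065300 to 101065378 and 101065598 to 101065667. For all 14 lists, the counts adjusted over the list alone equalled those adjusted over all miRNAs tested.

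**Figure D4:**
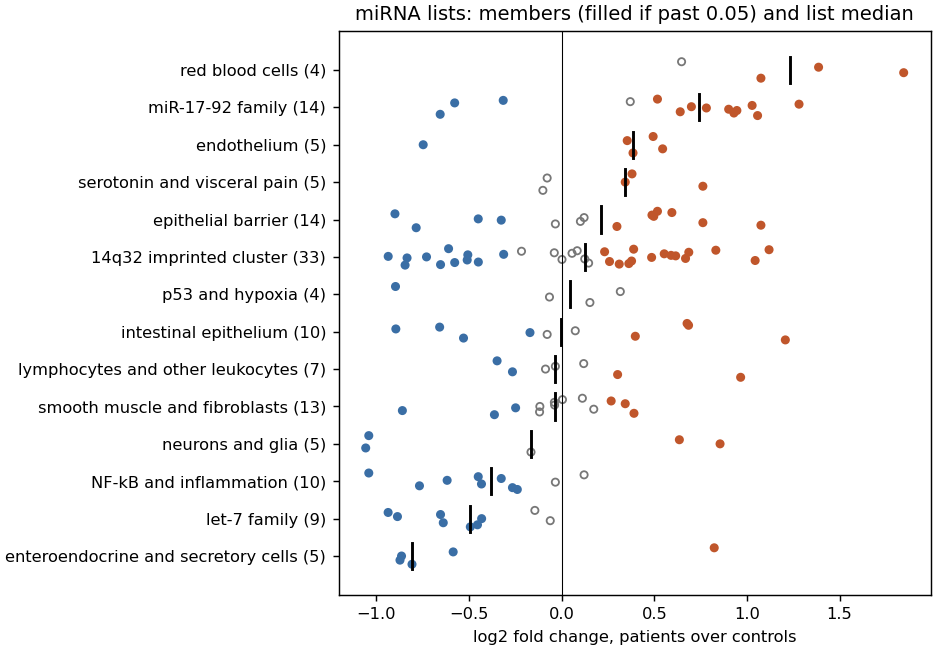
Log2 fold change of patients over controls for the tested members of 14 lists (number of members in brackets). Points are miRNAs, filled orange (higher) or blue (lower) when past an adjusted p of 0.05 in edgeR and open when not, and black bars are list medians, from −0.81 for enteroendocrine and secretory cells to 1.23 for red blood cells.

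Both arms of a precursor are cut from a single transcript, although some mature miRNAs come from several precursors whose counts were summed. Among 70 precursor names with both arms at a mean of at least 10 CPM, both arms differed for 42, and in 24 of these (57.1%, exact 95% interval 41.0% to 72.3%) they went in opposite directions. With library totals only this was 21 of 48. Over the 66 names whose arms were listed on the same single precursor, it was 21 of 39 (53.8%, exact 95% interval 37.2% to 69.9%). For miR-140 the 5p arm rose (log2 fold change 0.85) and the 3p arm fell (−0.55), and for miR-28 the 5p arm rose (0.54) and the 3p arm fell (−0.76). The arms of miR-192 and let-7i, each with a single precursor, also parted.

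**Figure D5:**
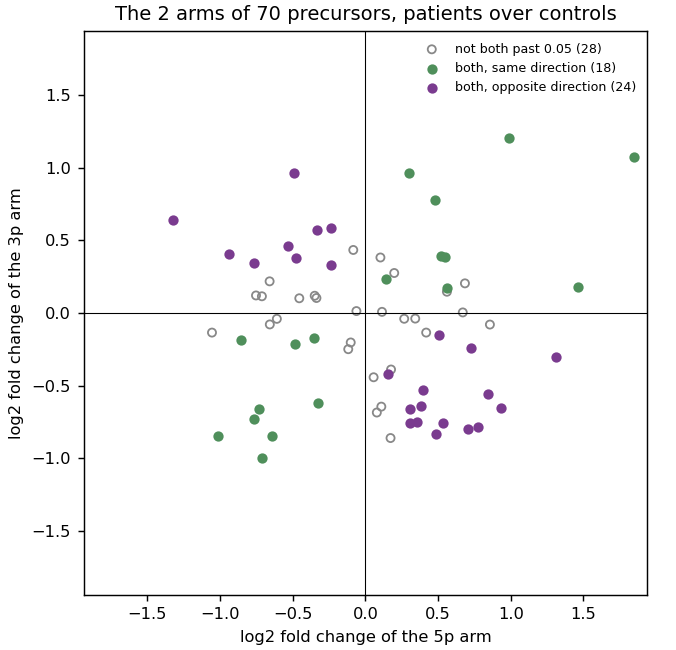
Log2 fold change of the 5p arm (x axis) against that of the 3p arm (y axis) for 70 precursor names. Purple points are the 24 whose arms both passed an adjusted p of 0.05 in opposite directions, green points the 18 in the same direction, and open points the 28 in which at most 1 arm passed.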

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

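Thinned libraries, the GC trend, omission of the furthest library of each group, rows kept apart and the red blood cell score were chosen after the data were seen. The count of 351 miRNAs past the threshold lay between 314 and 398 over the alternatives run, with 3 exceptions. The 314 were of 441 tested in thinned libraries, and the 398 were of 556 tested with rows kept apart. The stricter filter gave 245 of the 310 miRNAs it left, no filter gave 442 of 1998, and 179 differed at least 1.5-fold, by construction of that threshold. With the leading number of the title as a factor 339 were called and with 8 surrogate variables 373, and 334 and 337 of the 351 kept call and direction. Library totals only, which leave out the TMM factors (mean 1.11 in patients, 0.841 in controls), called 390: 252 of the 351 kept call and direction, 92 lost their call, 131 were new, and 43 changed sign, 7 of them with a call in the other direction. Among the miRNAs named, miR-21-5p then stood at 0.084, miR-26a-5p at 0.16, miR-200b-3p at 0.24, miR-1-3p at 0.039, miR-146a-5p at 0.13, miR-342-5p at 0.051 and miR-103a-3p at 0.30 on the log2 scale. miR-486-5p was 1.09 with library totals only, with a call, but −0.28 by the rank-sum permutation. Its mean was higher but its median lower in patients (215 against 333 CPM), so a comparison of means and one of ranks can part. The cause was not tested further. With the red blood cell score miR-486-5p was −0.90 and miR-144-3p −0.0044. That score is the mean of the tested red blood cell miRNAs, these included, so it takes out their shared difference by construction. With the direction kept, miR-200b-3p lost its call in 12 alternatives, miR-144-3p in 8 and miR-342-5p in 4. Each also changed sign in 1 more, so that its call did not hold there either. This was library totals only for miR-200b-3p and miR-342-5p, and the red blood cell score for miR-144-3p. Of the lists, 2 passed camera, against 1 with library totals only (miR-17-92 family), 4 without a filter, 0 with an estimated correlation, 8 by fry, which asks another question, and 1 with the red blood cell score (let-7 family); the cause was otherwise not tested. The difference in miRNAs detected was 1.65 without thinning (permutation p = 0.934), where the control libraries were the deeper ones. No library fell below the minimum total set for an alternative without shallow libraries, and the values are counts, so those alternatives were not run. No paired analysis was possible because the labels give no replicate numbers shared by the groups; numbers in accession order only name libraries. Depth limits the rare entries: 2069 miRNAs with few or no counts were not tested.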

Other observations

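The count of opposite arms, the arms on a single precursor, the direction of the muscle and epithelium members, the thinned libraries, the GC trend, the neighbouring precursors and the lists of other organs, squamous epithelium and entries on small RNA genes were tests chosen after the data were seen. miR-30a-5p and the other miRNAs outside the lists, and the clusters, were picked after their values were seen.

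Outside the lists, miR-30a-5p, abundant in epithelium, fell from 6037 to 2986 mean CPM (log2 fold change −1.02, SE 0.09; edgeR, adjusted p = 1.23e-15), and miR-378i fell from 894 to 398 CPM (log2 fold change −1.17). miR-590-3p (log2 fold change 1.32) and miR-4521 (1.10) rose. Several clusters with a shared transcript parted when each precursor was taken by 1 arm. miR-25-3p and miR-106b-3p fell (log2 fold changes −0.58 and −0.66) while miR-93-5p, from the precursor between theirs, rose (0.52). However, miR-106b-5p, the other arm of its precursor, rose (0.93), and miR-25-3p did not pass with library totals only. miR-27a-3p rose (0.64) and miR-23a-3p fell (−0.37, but 0.032 with library totals only), and miR-221-3p rose (0.38) and miR-222-3p fell (−0.23, but 0.19 with library totals only). miR-195-5p and miR-497-5p rose together (0.71 and 0.91), although miR-195-3p fell (−0.80). miR-29a-3p and miR-29b-3p also rose together (0.50 and 0.49). Of 66 pairs of neighbouring precursors within 10 kb, both members differed in 41, and 17 of these went in opposite directions. Each precursor was taken by its arm with the higher mean CPM, so differences between arms and between neighbours are mixed in this count. miR-205-5p and miR-203a-3p, the only pair of miRNAs so compared, did not correlate detectably over the 37 patient libraries (Pearson r = −0.050, permutation p = 0.772; Spearman rho = −0.019, permutation p = 0.911; r = 0.044 without the 2 furthest libraries).

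The first pattern is the breadth of the difference, 351 of 519 miRNAs. Chance is argued against, since only 1 of 100 splits of the libraries, the real split, gave as many, the smallest share possible here. The highest of the others gave 46. These splits cannot tell disease from any other difference between the groups. Depth and precursor GC content are each argued against as the whole cause. With thinned libraries 314 of 441 tested miRNAs were called, and after a GC trend was removed 347 of 519 were. A shift between muscle with stroma and epithelium as the whole cause is argued against by the 14 called members of those lists. Of these, 7 went as a gain of muscle requires and 7 the other way (10 and 8 with library totals only). The exact 95% interval of the share, 23.04% to 76.96%, takes members as independent. Several of them share a cluster, so the interval is too narrow. Whether such a shift was a part cannot be told, since the tissue score (−0.041 ± 0.477 in patients, 0.072 ± 0.494 in controls, SD; permutation p = 0.397) was built from these miRNAs and, as a covariate, with which 358 were called, took up little of the difference. Of other cell types a score was tried for red blood cells alone (344). Changed transcription as the whole cause is argued against by the 24 of 42 precursor names whose arms went in opposite directions, and by 21 of 39 with a single precursor for both arms, which share a transcript (exact 95% interval 37.2% to 69.9%). Across 70 precursor names, which are not independent replicates, the log2 fold changes of the arms correlated at 0.0064, against 0.471 for their deviations within groups. The difference was −0.465 (bootstrap interval −0.68 to −0.24). It was −0.42 (−0.66 to −0.18) for single precursors and −0.23 (−0.56 to 0.0037) for neighbouring precursors. The labels do not say whether patient and control libraries were prepared apart. As a hypothesis, a capture of single sequences that differed between these libraries would lower the correlation between groups in this way. Because every control carries the label of the other series, that explanation and an effect of the disease, which was not tested, both stay open and may add up.

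The second pattern is the fall of miR-1248, miR-1291 and miR-7641, entries that overlap or share 20 bases with small RNA genes, on which it was noticed (log2 fold changes −3.29, −2.35 and −2.53), whereas the other 3 such entries tested, miR-664a-5p, miR-664b-3p and miR-664a-3p, stood at −0.89, 0.10 and 0.34. Depth is argued against for miR-1248, which stayed between −3.44 and −2.89 over its alternatives, thinned libraries included. The 5 of these 6 entries still tested in thinned libraries had a median of −0.859. That median mixes in miR-664 entries, so it says little on the entries on which the pattern was noticed. Fewer fragments of structured RNA in the patient libraries may be a part, but over 17 detected entries other than those on which the pattern was noticed, the miR-664 entries included, the median log2 ratio was −0.5 (bootstrap interval −0.93 to 0.12), with 10 lower and 7 higher, so this could not be decided. A difference between patients and controls in these RNAs stays open and untested.

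The third pattern is miR-205-5p, with a count in 37 of 37 patient libraries and 9 of 21 control libraries. A small share of squamous epithelium in the patient biopsies may be a source. The bound set to count against it was met, since miR-203a-3p was lower in patients (upper 95% bound of its log2 fold change −0.646). That bound was wrong, because at 759 ± 351 CPM in controls, miR-203a-3p of the duodenum itself would hide such a share, and miR-944, with 65 counts in all, is too rare. Reads from libraries of other tissues could be another source, and 15 detected miRNAs of other organs had a median log2 fold change of −0.171, with 7 higher and 8 lower, which decides nothing although it lay below the bound set, since a single tissue need not carry these miRNAs. Neither source can be told apart from a higher level in the patients' duodenum, which was not tested.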
